A study of Mus musculus with 6 samples.

How the data were processed

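RNA from sorted bone marrow stem cells in 3 wildtype and 3 Irf8 knockout samples was amplified from small amounts with a whole-transcriptome kit and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The values deposited by the authors are log2 expression values, 1 per probe set and array. RMA, Affymetrix Expression Console and Partek are named without versions per the submitters' processing notes, and the settings and the test the authors used are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes, which compresses differences of dim probe sets. The scale was read from the values. Array medians between 4.85 and 4.96 show that final values were not forced to 1 distribution.

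Of 45037 probe sets, 34945 named 1 gene, 932 named several and 9160 were unnamed in the platform annotation used; 34741 matched a gene in the RefSeq table by Entrez number and 0 symbols changed. Only probe sets with 1 gene were used for genes, 18193 in all, and for the 9010 genes with several probe sets the one with the highest mean over all arrays stood for the gene. No filter on level was applied. No coordinates are given because the sources name no genome build. The planned check of control probe sets at the 3 prime and 5 prime ends was not made, since the table used here holds 0 of them.

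Samples were grouped by genotype from their titles. Knockout was compared with wildtype in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a mean-variance trend, and adjusted p means Benjamini-Hochberg over all genes, with a threshold of 0.05. Of 28 gene lists 27 were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the 27 lists; Xist and the Y-linked genes were described only. Alternatives were camera with an estimated correlation, and fry, which asks if a list moves 1 way without comparing it with other genes. The 28 lists, the settings listed below, their tests and the rule for naming genes were fixed before the data were examined, apart from additions named as such. The rule names Irf8, then up to 10 genes in each direction whose groups do not overlap and whose higher group mean lies above the median level, by size among those past the threshold and otherwise by smallest unadjusted p, and from each list up to 2 members with the smallest unadjusted p where none passes. Gene models without a proper name were skipped. The p-values rest on the spread between the 3 samples per group, which the labels call biological replicates without naming animals.

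The fit was tested on simulated data built on these 18193 genes, with 200 changed genes in each of 10 runs. The share of changed genes called was 6.6% at 2-fold, 27.2% at 4-fold, 49.6% at 8-fold and 65.2% at 16-fold, with 3.7 false calls per run. A list of 25 genes shifted by log2 1 was called in 10 of 10 runs with the preset correlation and in 0 with the estimated one. At a shift of log2 2 these numbers were 10 and 5, and at log2 0.5 they were 0 and 0. Simulated genes varied independently, whereas the real neutrophil list had an estimated correlation of 0.264. These runs therefore cannot show how the preset correlation behaves on correlated lists.

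Arrays were compared by Pearson correlation across genes, which are not independent replicates. The mean correlation was 0.903 within wildtype, 0.857 within knockout and 0.877 between groups, and knockout replicate 3 had the lowest mean correlation with the others, 0.845. Array medians averaged 4.90 in wildtype and 4.92 in knockout (exact permutation p = 0.7, two-sided), and mean correlations with the other arrays 0.887 and 0.869 (p = 0.3); 0.1 is the smallest p that 3 against 3 allows, so these tests could not show a difference. Alternatives covered the moderation, array weights, the choice of probe set, filters on level, scaling, a replicate block, a sex term and leaving out each array. Lists of other neutrophil genes, azurophil and later granule genes and imprinted growth genes were added after the first results were seen, with the alternatives and tests named as such in the closing section. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.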

Results

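Gene expression was measured in long-term haematopoietic stem cells sorted from mouse bone marrow, with 3 arrays from wildtype mice and 3 arrays from mice labelled as knockouts of Irf8, an interferon regulatory factor needed for monocyte and dendritic cell development. The sorted cells carried no lineage markers and no CD48, and carried Sca-1, c-kit and CD150. The labels place all 6 samples at 3 weeks, call them biological replicates and record no treatment. The deposited table held log2 values of 45037 probe sets per array, and array medians ran from 4.85 in knockout replicate 1 to 4.96 in knockout replicate 2. The number of arrays limits the precision of every value. The median standard error of a knockout minus wildtype difference was 0.46 on the log2 scale over 18193 genes. The comparison asks which genes differ between stem cells labelled wildtype and Irf8 knockout.

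Irf8 itself was not lower in the arrays labelled knockout. The brighter of its 2 probe sets read 5.52 ± 0.79 in wildtype and 5.93 ± 0.89 in knockout (log2, SD, n = 3 each), a difference of 0.41 with a standard error of 0.60 and an adjusted p of 0.92 in limma. The other probe set read 4.41 ± 0.58 in wildtype and 4.64 ± 0.83 in knockout, and both lay near or under the median gene level of 5.81. Where these probes lie relative to the removed part of the gene is not given in the sources used here, so the Irf8 signal does not test the labels, and directions below refer to arrays as labelled. Xist, the RNA that silences an X chromosome in females, read above 10.6 in all 3 of its probe sets in wildtype replicate 3 and knockout replicate 1. In the other 4 arrays Xist read between 2.67 and 3.81 except for 7.60 in 1 probe set of wildtype replicate 1, and the Y-linked gene Eif2s3y, a translation factor subunit, read between 7.06 and 9.95 in its brighter probe set. Arrays of both patterns were present in each group, in 1 wildtype and 1 knockout array for the Xist pattern.

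Genes of neutrophils and their granules were higher as a group in the knockout arrays. The median log2 difference over 25 measured genes was 2.01, and 21 genes had a difference above 0. S100a9 read 11.16 ± 0.28 in wildtype and 13.17 ± 0.68 in knockout, and its partner S100a8 read 10.54 ± 0.56 and 12.66 ± 0.63 (SD, n = 3 each); the pair forms the calcium-binding protein calprotectin of neutrophils. Cebpa, a transcription factor of granulocyte fate chosen here after its values were seen, read 3.62 ± 0.16 in wildtype and 7.68 ± 2.11 in knockout. All 3 knockout arrays lay above all 3 wildtype arrays for 7 of the 25 genes and below them for 0, where chance gives 10% over both directions. The group passed limma's camera test with the preset correlation (adjusted p = 7.18e-06 over 27 lists) and did not pass with an estimated correlation (adjusted p = 0.584). Taken singly, 0 of its genes passed over all genes, and 3 did when adjusted over the list alone. Knockout replicate 3 stood apart: the list's median difference from the wildtype mean was 3.60 there, against 1.19 in knockout replicate 1. Knockout replicate 2, at 0.172, was level with wildtype replicate 1, at 0.168. Without knockout replicate 3 the median was 0.70, and the adjusted p was 0.000888 with the preset correlation and 0.316 with an estimated one.

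**Figure D1:**
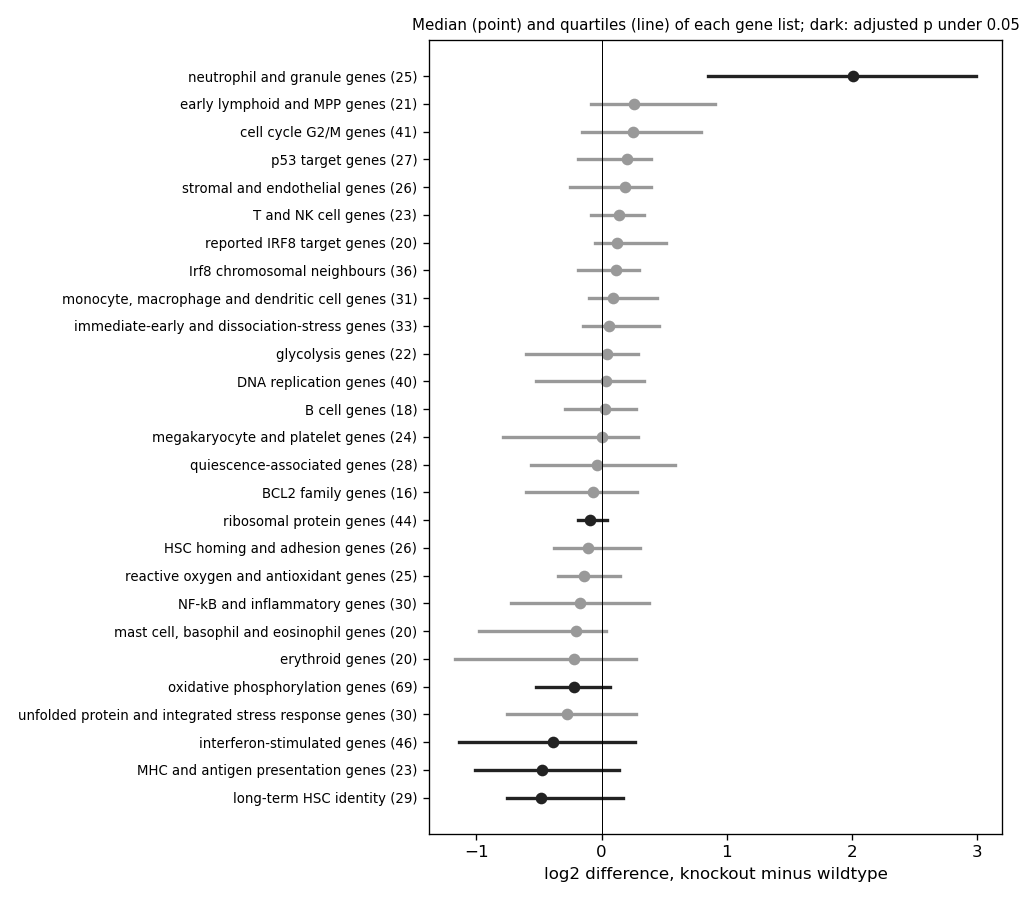
Median (point) and quartiles (line) of the log2 difference, knockout minus wildtype, over the measured genes of each of 27 gene lists; the number of genes stands in parentheses and dark marks show lists with an adjusted p under 0.05 in camera with the preset correlation. The neutrophil list has a median of 2.01, and the 5 other dark lists have medians between -0.48 and -0.09.

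Genes of antigen presentation and of the interferon response were lower as groups in the knockout arrays. The 23 MHC and antigen presentation genes had a median log2 difference of -0.47, with 16 genes below 0. H2-Eb1, a chain of an MHC class II molecule, read 8.41 ± 0.79 in wildtype and 5.85 ± 0.07 in knockout, a difference of -2.56 (SE 0.55). H2-D1, an MHC class I heavy chain, read 11.97 ± 0.12 and 10.96 ± 0.29, a difference of -1.004 (SE 0.21), while 2 of its other probe sets gave 0.18 and 0.01; all 3 are of a type open to cross-hybridisation. The 46 interferon-stimulated genes had a median of -0.38, with 31 below 0 and 15 above. Rsad2, the antiviral protein viperin, read 8.60 ± 0.50 in wildtype and 5.81 ± 0.62 in knockout, and Irgm1, an interferon-induced GTPase, differed by -1.60 (SE 0.52). Other members went the opposite way, among them Irf7 at 0.31 and Oas2 at 1.03. Each list had an adjusted p of 0.00142 in camera with the preset correlation; with an estimated correlation the adjusted p was 0.216 for the MHC list and 0.584 for the interferon list. Over all genes 0 members of either list passed, and adjusted over the list alone 2 MHC genes and 0 interferon genes did. Knockout replicate 3 had the lowest MHC median, -0.56 from the wildtype mean. Knockout replicate 2 stood at -0.283, and knockout replicate 1 at -0.057, level with -0.056 in wildtype replicate 2. Without knockout replicate 3 the MHC median was -0.19 (adjusted p = 0.0376 with the preset correlation and 0.316 with an estimated one). With the mean of each gene's probe sets the MHC median was -0.20 (adjusted p = 0.0307), with H2-D1 at -0.345 and Rsad2 at -1.59. Without wildtype replicate 3 the interferon median was -0.01 and the list no longer passed (adjusted p = 0.0703), and among genes above the median level it did not pass either (adjusted p = 0.292).

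Lists of long-term stem cell identity, oxidative phosphorylation and ribosomal protein genes also had medians below 0 and passed with the preset correlation. The 29 stem cell identity genes had a median of -0.48, with 20 below 0: Procr, the endothelial protein C receptor that marks stem cells, differed by -0.75 (SE 0.36) and Ndn, a growth suppressor, by -1.07 (SE 0.55; -0.42 without knockout replicate 3 and 0.26 in another probe set), whereas Hlf, Meis1 and Tek differed by 0.15, 0.34 and 0.38. The 69 oxidative phosphorylation genes had a median of -0.22, with 48 below 0, and the median was -0.13 without knockout replicate 3 and -0.34 without wildtype replicate 3. Ndufa4 differed by -0.60 (SE 0.21), while Cox7c, a subunit of cytochrome c oxidase, differed by 2.97 (SE 0.41) in the opposite direction. The probe sets standing for Procr, Ndn and Cox7c are of a type open to cross-hybridisation. The 44 ribosomal protein genes had a median of -0.09 and a mean of -0.015, with 30 below 0 and 14 above. Among them 5 genes were lower and 4 higher in knockout without overlap between groups. Rplp2 differed by -0.22 (SE 0.05) and Rpl11 by -0.46 (SE 0.13). The adjusted p with the preset correlation was 0.0496, 0.00142 and 0.0171 in that order, and with an estimated correlation the adjusted p was 0.821, 0.216 and 0.584. Over all genes 0 members passed, and adjusted over the list alone 1 oxidative phosphorylation gene did, Cox7c. Among genes above the median level the 3 lists did not pass (adjusted p = 0.292, 0.0727 and 0.166). Quantile normalization ended the calls of stem cell identity and ribosomal genes (adjusted p = 0.0915 each), and that of stem cell identity also ended with arrays centred on their median (adjusted p = 0.0628) or without shared genes (adjusted p = 0.21). The stem cell identity median was 0.33 and -0.46 in knockout replicates 1 and 2 and -1.40 in knockout replicate 3; without that array it was -0.08 and the direction of the test turned (adjusted p = 0.876), and the list was also lost without wildtype replicate 1 (adjusted p = 0.112) or wildtype replicate 2 (adjusted p = 0.161). The ribosomal list was lost without wildtype replicate 3, knockout replicate 2 or knockout replicate 3, with adjusted p of 0.0591, 0.07 and 0.125 and medians of -0.08, -0.05 and -0.04.

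**Figure D2:**
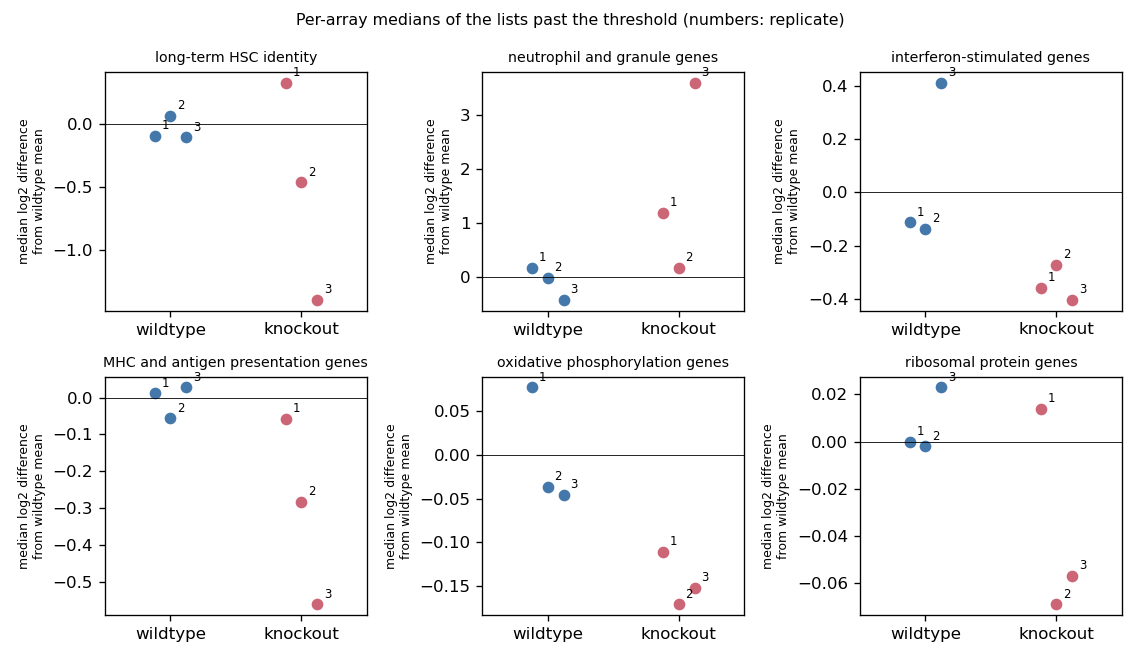
Median log2 difference from the wildtype mean, per array, of the 6 gene lists with an adjusted p under 0.05 in camera with the preset correlation; each point is 1 array, numbered by replicate, and the vertical scale differs between panels. Knockout replicate 3 is farthest from the wildtype arrays for the neutrophil list at 3.60, for the MHC list at -0.56 and for the stem cell identity list at -1.40.

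Lists of other lineages did not pass over all 6 arrays, and 0 of their genes passed over all genes. The early lymphoid and multipotent progenitor genes had a median of 0.26 (adjusted p = 0.217), with Flt3, a cytokine receptor of progenitors, at 6.58 ± 0.37 in wildtype and 9.03 ± 1.34 in knockout, and Cd27 at a difference of -0.85 (-0.55 without wildtype replicate 2). The erythroid genes had a median of -0.22 (adjusted p = 0.0627), with Gfi1b, a repressor needed for red cell and platelet formation, at 10.49 ± 0.23 and 8.25 ± 0.76, and Klf1, an erythroid transcription factor, at a difference of -2.21. Among megakaryocyte and platelet genes, with a median of 0.00 (adjusted p = 0.217) and a mean of -0.46, Thbs1 (thrombospondin) read 7.80 ± 0.43 and 4.99 ± 0.42 and was the 1 gene that passed adjusted over the list alone, and Clec1b differed by -1.95 (-1.29 without wildtype replicate 1). The monocyte, macrophage and dendritic cell genes had a median of 0.09 (adjusted p = 0.355) with the chemokine receptor gene Ccr2 at -1.03, which was -0.58 without wildtype replicate 3, -0.26 with the mean of probe sets and above 0 in 2 other probe sets. The B cell genes had 0.02 (adjusted p = 0.826) with Cd79b at -1.41 (-0.82 without wildtype replicate 2) and Rag1 at 0.25 (0.12 without knockout replicate 3). The T and NK cell genes had a median of 0.14 (adjusted p = 0.348) with Tbx21 at 0.53 and Ncr1 at 0.42. Rag1, Tbx21 and Ncr1 read far under the median gene level of 5.81, at 2.68, 3.46 and 3.95 in knockout. The mast cell, basophil and eosinophil genes had -0.20 (adjusted p = 0.157) with Mitf at -1.88 (-1.05 with the mean of probe sets) and Mcpt8 at -2.00. Without wildtype replicate 1 Mcpt8 differed by -3.35, and without wildtype replicate 2 it differed by -0.92, the list median was 0.05 and the direction of the test turned. The stromal and endothelial genes had a median of 0.19 (adjusted p = 0.743) with Flt1 at 0.68 (0.41 without knockout replicate 3, 1.02 without knockout replicate 2 and 0.21 with the mean of probe sets) and Emcn at -1.59 (-2.40 without knockout replicate 1). Of the monocyte list 10 of 31 genes lay above the median gene level, of the B cell list 5 of 18, of the T and NK list 4 of 23 and of the mast cell list 3 of 20. Most members of those lists thus had little room to be lower. With the preset correlation some passed under other settings. With the mean of each gene's probe sets erythroid genes (median -0.32, adjusted p = 0.0307) and early lymphoid genes (0.26, adjusted p = 0.0434) did. Erythroid genes also passed without wildtype replicate 3 (-0.20, adjusted p = 0.0391) or knockout replicate 3 (-0.33, adjusted p = 0.0256), and had a median of -0.08 without knockout replicate 1 (adjusted p = 0.326). Mast cell genes passed without wildtype replicate 1 (-0.35, adjusted p = 0.0361) or wildtype replicate 3 (-0.32, adjusted p = 0.0407), and megakaryocyte genes without wildtype replicate 2 (-0.185, adjusted p = 0.0151). With an estimated correlation under the same settings none of these lists passed, with adjusted p of 0.432, 0.659 and 0.316 for erythroid, 0.649 for early lymphoid, 0.924 and 0.74 for mast cell and 0.845 for megakaryocyte genes.

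The genes beside Irf8, its reported targets and the remaining pathway lists did not pass over all 6 arrays. The reported IRF8 targets had a median of 0.12 (adjusted p = 0.708), which was -0.14 without knockout replicate 3, with Cybb, a subunit of the phagocyte oxidase, at a difference of 3.03 and the Ras regulator Nf1 at -1.65. Cybb read 5.81, 3.67 and 9.84 in the 3 knockout arrays and differed by 1.335 without knockout replicate 3. Nf1 differed by -2.52 without wildtype replicate 3, by -0.48 with the mean of probe sets and by 0.32 in another probe set. The genes beside Irf8 on its chromosome had a median of 0.12 (adjusted p = 0.826), with Foxc2 at 0.44 and Gse1 at -1.15 (-0.30 with the mean of probe sets). Foxc2 read 2.43 in wildtype and 2.87 in knockout, far under the median gene level of 5.81. Cell cycle genes of the G2/M phase had a median of 0.25 (adjusted p = 0.743) with Nusap1 at -3.00 and Ube2c at -1.49 (-0.94 without knockout replicate 1). The G2/M median was 0.08 and Nusap1 differed by -1.385 with the mean of probe sets, and another probe set of Nusap1 gave 0.23. DNA replication genes had 0.03 (adjusted p = 0.348) with the sliding clamp Pcna at a difference of -0.86 and the nuclease Fen1 at -0.44, and quiescence-associated genes -0.04 (adjusted p = 0.708) with Tob1 at 1.15 (0.41 with the mean of probe sets) and Tcf15 at -1.36 (-0.89 without wildtype replicate 3).

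The p53 targets had a median of 0.20 (adjusted p = 0.743) with Apaf1, a part of the apoptosome, at 1.43 (0.82 with the mean of probe sets), and the BCL2 family -0.07 (adjusted p = 0.743) with Bnip3 at 1.54 and Pmaip1, a member of both lists, at 0.26. Pmaip1 read 2.22 in wildtype and 2.49 in knockout, far under the median gene level of 5.81. The unfolded protein and integrated stress response genes had a median of -0.27 (adjusted p = 0.144) with Pdia4 at -1.51 and Edem1 at 1.29. Pdia4 differed by -0.68 and Edem1 turned to -0.92 with the mean of probe sets, and other probe sets gave 0.14 for Pdia4 and -3.13 for Edem1. The NF-kB and inflammatory genes had -0.18 (adjusted p = 0.355) with Nfkbie at -2.49 and Cd69 at 1.22. The immediate-early and dissociation-stress genes had a median of 0.06 (adjusted p = 0.487) with the chaperone Hspa8 at 0.23 (-0.16 with the mean of probe sets) and Klf2 at 1.33. The homing and adhesion genes had a median of -0.11 (adjusted p = 0.575) with Alcam at 1.04 and Mcam at -0.25. Mcam also read far under the median gene level, at 2.70 in wildtype and 2.45 in knockout. The glycolysis genes had 0.04 (adjusted p = 0.708) with the glucose transporter Slc2a1 at -1.06 (-0.67 without wildtype replicate 3) and Pdk3 at -1.59 (-0.74 without knockout replicate 3), and the reactive oxygen and antioxidant genes -0.14 (adjusted p = 0.348), where Ncf4, an oxidase subunit, differed by 2.09 and the peroxidase Prdx2 by -1.43. Over all genes 0 members of these lists or of those in the paragraph before passed. With the preset correlation unfolded protein genes passed with the mean of probe sets (-0.28, adjusted p = 0.0307) and without wildtype replicate 3 (-0.40, adjusted p = 0.0153). DNA replication genes passed without wildtype replicate 3 (-0.14, adjusted p = 0.0156) and immediate-early genes without knockout replicate 3 (0.20, adjusted p = 0.00993). With an estimated correlation under the same settings the adjusted p was 0.432 and 0.421 for unfolded protein, 0.421 for DNA replication and 0.316 for immediate-early genes. The mean had the opposite sign to the median for the Irf8 neighbours (-0.03), B cell (-0.12), megakaryocyte (-0.46), DNA replication (-0.07), glycolysis (-0.18) and reactive oxygen genes (0.06), and for B cell, megakaryocyte, DNA replication and glycolysis genes the test took the sign of the mean.

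Gene by gene, no difference passed the threshold after adjustment for the number of genes tested. With limma and Benjamini-Hochberg adjustment 0 of 18193 genes passed, and the smallest adjusted p was 0.0719, for Zfp229, a zinc finger gene singled out after its value was seen. At an unadjusted p under 0.05 there were 880 genes, 437 higher and 443 lower in knockout, where 910 are expected by chance, and the groups did not overlap for 10.9% of genes (1214 higher and 774 lower), where chance gives 10%. Among genes above the median level 186 were higher and 342 lower at an unadjusted p under 0.05. The genes named next had groups without overlap and a higher group mean above the median level, which leaves out Zfp229 (5.27 in wildtype, difference -2.98). Among them, those with the smallest unadjusted p and higher values in knockout were Pomk (difference 3.80, SE 0.50), a kinase that modifies dystroglycan, Cox7c, the potassium channel Kcnj13 (2.78), S100a9, Tmem81 (1.72), S100a8, Qrsl1 (3.65), Elmod3 (2.74), Zfp959 (2.74) and Lamtor4 (2.13), a part of the Ragulator complex on lysosomes. In the other direction were Runx1t1 (-4.66), a corepressor and fusion partner of RUNX1, the dehydrogenase Acad11 (-4.48), Zfp612 (-3.10), Rbm12 (-5.25), Otos (-2.95), Oas1c (-2.39), of the oligoadenylate synthetase family, Thbs1 (-2.81), Tox (-2.89), a regulator of lymphocyte development, the noncoding RNA Rian (-4.39) and Vps33a (-3.09). The adjusted p of these 20 ran from 0.438 to 0.88. Pomk, Cox7c, S100a8, Qrsl1 and Elmod3 were read by probe sets of a type open to cross-hybridisation. With the mean of each gene's probe sets the differences were smaller for Rbm12 (-1.965), Runx1t1 (-0.72), Rian (-1.46), Acad11 (-2.68), Zfp612 (-1.73), Thbs1 (-1.51), Tox (-1.39), Vps33a (-1.67), Qrsl1 (1.82) and Elmod3 (0.82). Other probe sets of Runx1t1, Rian, Qrsl1 and Elmod3 gave the opposite sign. For 3985 genes with 2 probe sets above the median level, the differences of the 2 correlated with r = 0.07. Other divisions of the arrays gave 0.037 to 0.114, so most single differences are not backed by another probe set. Among other divisions of the 6 arrays into groups of 3, up to 7 lists passed camera with the preset correlation, against 6 for genotype.

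**Figure D3:**
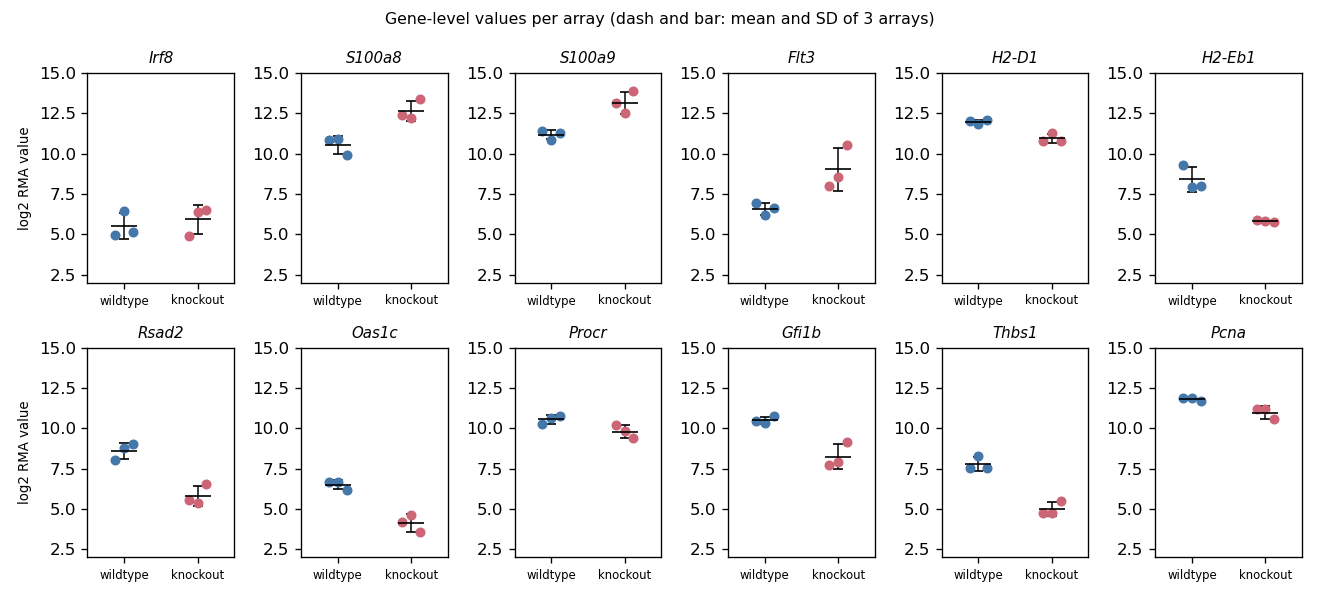
Gene-level log2 values of 12 named genes in the 3 wildtype and 3 knockout arrays; points are arrays, and the dash and bar give the mean and SD of 3 arrays. Irf8 overlaps between groups, while S100a8 and S100a9 are higher in all 3 knockout arrays and H2-Eb1, Rsad2 and Thbs1 are lower in all 3, none of them past the adjusted threshold.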

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

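Counts at an unadjusted p, lists without shared genes, the estimated correlation together with another setting and the split of the neutrophil list were chosen after seeing the data; the other settings were planned. No gene passed in limma under the planned settings except Zfp229, the 1 gene called with the mean of each gene's probe sets and with arrays centred on their median (adjusted p = 0.047 in each; smallest adjusted p over the other settings 0.0652 to 0.58), and 880 genes had an unadjusted p under 0.05. With 1 array left out, counts at an unadjusted p under 0.05 ran from 689 without wildtype replicate 1 to 1204 without knockout replicate 2. The Irf8 difference ran from 0.13 to 0.92 when arrays were left out. Deviations of wildtype and knockout arrays with the same replicate number showed no correlation (r = -0.02, -0.01 and -0.01). These values cannot exclude a pairing, since deviations of 2 probe sets of a gene above the median level also gave only r = 0.07. With the replicate block 0 genes passed, 838 had an unadjusted p under 0.05 and the same 6 lists were called.

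The number of lists called was 6, became 2 among genes above the median level, 4 with quantile normalization, 5 with centring, 9 with the mean of probe sets, 5 to 8 with 1 array left out, and 0 with an estimated correlation or with fry. The mean of probe sets added early lymphoid (0.263), erythroid (-0.323) and unfolded protein genes (-0.282), and leaving out wildtype replicate 3 gave 8 lists, 4 of them added and 2 lost. With an estimated correlation 0 lists passed under each of 12 other settings of the lists, 6 of them with 1 array left out (smallest adjusted p 0.278 to 0.865). With fry the adjusted p was 0.497 for neutrophil genes, 0.242 for MHC genes, 0.544 for interferon-stimulated genes, 0.414 for oxidative phosphorylation, 0.603 for ribosomal proteins and 0.782 for stem cell identity, at medians of 2.01, -0.47, -0.38, -0.22, -0.092 and -0.48, which the estimated correlation leaves as they are. Fry's mixed test, which counts changes in either direction, called 5 lists. They were oxidative phosphorylation (adjusted p = 0.00788), MHC and erythroid (0.0214 each), and ribosomal protein and early lymphoid genes (0.0381 each). In that test the neutrophil (0.0909), interferon-stimulated (0.075) and stem cell identity lists (0.744) did not pass. Among genes above the median level the medians were -0.48 for stem cell identity and -0.26 for interferon-stimulated genes. They were -0.24 for oxidative phosphorylation and -0.093 for ribosomal protein genes, and none of these lists passed. In that order 27 of 29, 35 of 46, 68 of 69 and 41 of 44 genes were kept, so most members stayed. The genes they were compared with changed too: in limma 186 of that set were higher and 342 lower at an unadjusted p under 0.05. Quantile normalization ended the calls of stem cell identity (-0.42) and ribosomal proteins (-0.053), centring that of stem cell identity (-0.50), and leaving out shared genes that of stem cell identity (-0.42). The cause was not tested for these.

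The direction of the test turned for stem cell identity without knockout replicate 3 (-0.084, adjusted p = 0.876); the others that turned had not passed. With the mean of probe sets these were IRF8 targets (0.037), B cell (0.135), G2/M (0.083), immediate-early (0.023), p53 (-0.033) and BCL2 genes (0.024). Among genes above the median level they were Irf8 neighbours (0.065), IRF8 targets (-0.017), stromal (0.165), NF-kB (-0.149), homing (0.104) and glycolysis genes (0.045), and with fry B cell (0.025) and homing genes (-0.108). When single arrays were left out the medians ran from -0.837 to -0.084 for stem cell identity, -0.537 to -0.007 for interferon-stimulated, -0.139 to -0.04 for ribosomal, -0.185 to 0.241 for megakaryocyte, -0.349 to 0.052 for mast cell, 0.046 to 0.196 for Irf8 neighbour, -0.17 to 0.15 for B cell, 0.034 to 0.197 for immediate-early, 0.02 to 0.24 for p53, -0.003 to 0.482 for G2/M, 0.025 to 0.254 for stromal, -0.261 to -0.013 for NF-kB and -0.195 to 0.236 for quiescence genes. For lists whose test kept its direction they ran from -0.141 to 0.238 for IRF8 targets, -0.351 to -0.077 for erythroid, 0.146 to 0.333 for early lymphoid, 0.071 to 0.191 for monocyte, 0.041 to 0.208 for T and NK cell, -0.172 to 0.027 for DNA replication, -0.398 to -0.121 for unfolded protein, -0.202 to 0.084 for BCL2, -0.298 to 0.061 for homing, -0.089 to 0.141 for glycolysis and -0.244 to -0.059 for reactive oxygen genes. Neutrophil, MHC and oxidative phosphorylation genes passed with the preset correlation and each array left out, and with an estimated correlation in none of these, at medians of 0.70 to 2.34, -0.57 to -0.19 and -0.34 to -0.13.

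Named genes kept their sign in 408 of 408 fits without 1 array. For genes whose groups do not overlap no other outcome was possible, and the others were picked by p from the same arrays. The count therefore says little about stability. With the mean of probe sets Hspa8 (-0.16) and Edem1 (-0.92) turned; genes that moved by over 1.5 times are given with their values in the report. Other probe sets gave the opposite sign for Qrsl1 (-0.017), Elmod3 (-1.10), Runx1t1 (1.05 and 0.053), Rian (0.14 and 0.12), Gse1 (0.93), Nf1 (0.32), Ndn (0.26), Ccr2 (0.058 and 0.209), H2-D1 (0.183 and 0.012), Nusap1 (0.23), Tob1 (-0.32), Hspa8 (-0.164, -0.057 and -0.65), Pdia4 (0.14), Edem1 (-3.13) and Alcam (-0.004). The cause was not tested for these. Whether signal over background limits them was not tested; deviations of a gene's probe sets correlated with r = 0.055 where the dimmer lay under the median level and 0.278 where it lay over 10.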

Other observations

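The tests on knockout replicate 3 alone, on B cell and monocyte markers, on sex, on imprinted genes and on gene counts over other splits were chosen after the results were seen; the tests on probe sets of the same gene and on list counts over other splits were set beforehand. The list of other neutrophil genes was compiled after the neutrophil result was seen and before its own values were. Within the neutrophil list, the 8 azurophil granule genes, made early in granulocyte formation, had a median log2 difference of 1.84 with 7 above 0, and the 16 later granule and neutrophil genes had 2.06 with 14 above 0. Without knockout replicate 3 the medians were 0.79 and 0.99. Cd48, whose protein the sort excluded, read 7.60 and 9.42 in knockout replicates 1 and 2, against 3.55 in knockout replicate 3 and 3.13 to 4.54 in wildtype, and had an unadjusted p of 0.0811 in limma; it was singled out after its values were seen.

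The higher neutrophil genes in knockout may be RNA of mature neutrophils carried through the sort, whose lineage-negative gate would remove such cells. A list of 31 other neutrophil genes had a median difference of 0.585 (95% bootstrap interval 0.251 to 0.994, which treats genes as independent), in the direction that explanation needs, although camera gave p = 0.258 with an estimated correlation of 0.278, 9 of them lay above the median level and 0.10 was their median without knockout replicate 3. The 31 genes did not move together in knockout replicate 3. Fpr2 read 10.66 and Hp 10.84 there, against at most 4.21 and 6.87 in the other arrays. Cxcr2 at 3.70, Clec4e at 2.62 and Slfn4 at 3.85 were among those under the median gene level of 5.81 in that array. The abundant S100a9 read 12.50 or more in each knockout array. Knockout replicate 3 supplies most of the size, since the median of 2.01 became 0.702 without it. The list then still passed with the preset correlation (adjusted p = 0.000888) but not with an estimated one (adjusted p = 0.316). Neutrophil RNA, the influence of that array and a difference due to genotype all stay open.

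The lower MHC genes may likewise rest largely on knockout replicate 3, since their median of -0.47 became -0.19 without it. For interferon-stimulated genes the tables argue against that array as the cause, because their median was -0.365 without it and -0.38 with it, and the list passed with the preset correlation (adjusted p = 0.0414). That list did not pass with an estimated correlation over all arrays (adjusted p = 0.584) or without knockout replicate 3 (adjusted p = 0.706). Its median was -0.007 without wildtype replicate 3 (adjusted p = 0.0703 with the preset correlation). Fewer B cells, monocytes or dendritic cells in the knockout sorts, whose lineage-negative, Sca-1 and c-kit gate would remove such cells, cannot be told apart from a change within stem cells: most of those markers lie under the median level and had little room to be lower, with a lower 95% bound of -0.259 for the B cell median and a median of 0.084 (0.024 to 0.37) for monocyte and dendritic cell genes. Among genes above the median level the B cell median was -1.41 over 5 genes, and that of the monocyte, macrophage and dendritic cell list 0.42 over 10. These markers went in opposite directions, and neither list passed with the preset correlation (adjusted p = 0.565 and 0.0727). A difference due to genotype stays open.

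The scatter between arrays of a group may come largely from noise that differs between probe sets of the same gene, such as uneven amplification of little RNA. For 3985 genes with a pair of probe sets above the median level, the deviations from the group means correlated with r = 0.07 across genes, which are not independent replicates; probe sets can also read different transcript ends, so noise is not the only reading. Knockout minus wildtype differences of these pairs also correlated with r = 0.07, within the 0.037 to 0.114 of other splits into groups of 3. The 150 genes whose dimmer probe set lay over 10 gave r = 0.278 for the deviations. For their knockout minus wildtype differences r was 0.382, against 0.058 to 0.374 in other splits. Sex of the mice is argued against as the main cause of the scatter, since a sex term lowered the median residual SD by 5.66%, within the 2.91% to 7.32% that the same term gave for the 8 other pairs of 1 wildtype and 1 knockout array. With the sex term 0 genes passed for genotype and 3 for sex (Slc16a12, Fhit and Lig4, named after their values were seen). The same term for each of the 8 other pairs gave 0 passing genes for the pair. Xist and Eif2s3y, which set the term, differed by -6.39 and 4.65 between Y-pattern and Xist-pattern arrays. Neither passed for sex in limma (adjusted p = 0.72 and 0.626). The fit thus had little power for sex, and sex differences of single genes stay open.

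With 10 ways to split 6 arrays into equal groups, the splits are too few for a share under 0.05. At an unadjusted p under 0.05, 2 of the 10 splits gave as many genes, with 880 in the real split and 983 as the highest other. For lists, 4 of the 10 splits gave as many past the threshold with the preset correlation, with 6 in the real split and 7 as the highest other. The neutrophil median was 2.01 in the real split and at most 1.24 in size in the others, and the MHC median -0.47 against at most 0.415 in size. With the preset correlation the neutrophil list also passed in 4 of the 9 other splits (smallest adjusted p 0.000396) and the MHC list in 1 (adjusted p = 0.0244).

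Because the imprinted noncoding RNA Rian was among the genes with the lowest values in knockout, 15 imprinted growth genes were tested as a set, under the hypothesis that they are lower as a whole. The median was -0.11 (95% bootstrap interval over genes -1.07 to 0.53) and the camera p with an estimated correlation was 0.481, so the data leave the hypothesis undecided.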
